A study of Mus musculus with 12 samples.

How the data were processed

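RNA was sequenced from marginal zone B cells, the innate-like B lymphocytes that border the splenic marginal sinus. The cells came from wild-type and Trpm5-/- mice and were kept for 4 h without stimulus, with lipopolysaccharide (LPS, 10 µg/mL) or with an antibody against IgM (anti-IgM, 10 µg/mL). Each of the 6 groups held 2 libraries, 12 in all. Per the labels, total RNA was turned into full-length cDNA with a SMART-Seq HT kit, so small RNAs shorter than the library fragments are measured poorly. The labels do not say whether the 2 libraries of a group came from separate animals or cultures. Every p-value therefore measures the spread between these libraries, which may be technical only.

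The deposited files hold 1 value per gene symbol and library for 24346 symbols. The unit is not written in them and was taken as FPKM (fragments per kilobase of transcript, relative to the mapped total) because the authors name Cufflinks and because the values behave so: none is negative, and low values of a gene are multiples of a step that depends on the gene and the library. The submitters' processing notes name TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cufflinks 2.2.1 and the mm10 build. The annotation, the counting program, the mapped totals and the part of Trpm5 that is deleted are not given in the sources used here. The median ratio of each library to the geometric mean of all 12 lay within 1.008 and 1.015, so the values had already been scaled between libraries by the authors. No further scaling was applied.

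The FPKM of a library summed to between 563461 and 805373, and between 12737 and 13483 symbols were above 0. Total read counts are not given in the sources used here. Relative depth was read from the size of a 1-fragment step and ran from 0.644 to 1.06 of that of wild-type unstimulated replicate 1. Pearson r of log2 values between the libraries of a group, across genes, was 0.9589 to 0.9778, and 0 pairs of libraries were identical.

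Values were analysed as log2(FPKM + 1) for the 10797 genes with at least 1 FPKM in at least 2 libraries. A group-means model over all 12 libraries (limma 3.58.1 in R 4.3.3, eBayes with a mean-variance trend, 6 residual degrees of freedom) gave 11 comparisons. These were the genotype difference (Trpm5-/- minus wild type) in each condition and averaged over the 3 conditions, the response to LPS and to anti-IgM in each genotype, the interaction of genotype with each stimulus, and LPS against anti-IgM in wild-type cells. All tests were 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors beside log2 differences are standard errors of the model, and errors beside FPKM are standard deviations of 2 libraries. The model was tested on simulated data with 200 changed genes: for the genotype difference under LPS it recovered 37.3% of 1.5-fold, 73.1% of 2-fold and 100% of 4-fold changes, with 3 false calls among 143. For the interaction with LPS the shares were 31.3%, 64.2% and 87.9%, with 8 false calls among 130.

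Gene lists, the named-gene rule, the comparisons and most alternatives were chosen before the data were examined. The 32 lists covered calcium channels and pumps, the calcineurin-NFAT response, NF-kB targets, cytokines and chemokines, interferon-stimulated genes, immediate early genes, B cell activation surface proteins, the plasma cell programme, marginal zone identity, follicular identity, B cell receptor signalling, TLR4 signalling, ribosome biogenesis with MYC targets, cell cycle entry, mitosis, glycolysis, apoptosis regulators, the unfolded protein response, oxidative phosphorylation, a ubiquitous reference set, pan-B markers, markers of T cells, NK cells, macrophages and monocytes, neutrophils, dendritic cells, erythroid cells, platelets and stromal or endothelial cells, the neighbours of Trpm5 on chromosome 7, sex-chromosome genes, and mitochondrial, ribosomal and nuclear RNAs as signs of RNA quality. The 24 lists with at least 5 tested members went through camera with a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. Members called were counted with p-values adjusted over all genes and adjusted over the list alone. A camera p tests whether a list moved more than other genes.

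Named genes were Trpm5; the 10 largest rises and falls among called genes with at least 5 FPKM in the higher group and no overlap between the libraries compared, leaving out predicted gene models and antigen receptor segments; the 2 to 4 members of smallest p in each list described; and Il6, Cxcl10 and Il10 under LPS. Where fewer than 4 genes were called, the 5 genes of smallest p in each direction were taken. Positions are from GENCODE M21 on mm10, which gave 1 position for 23932 symbols, 666 of them through a RefSeq synonym. It gave several positions for 44 symbols and none for 370.

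Each result was recomputed with a pseudocount of 0.1, without the filter, with a mean of at least 5 FPKM, with median-of-ratios scaling, with quantile normalization, with only the groups compared, with a robust spread model, with library weights, with replicate number as a block, and leaving out each library in turn. The library weights came out equal for the 2 libraries of each group (0.866 to 1.09 between groups). That setting could therefore not single out a poor library. In a fit without a library, the remaining library of that group is assumed to vary like the others. A fit without the 116 tested genes of small RNAs was added after seeing the data, because their FPKM jumped between 0 and very high values. The labels do not say whether libraries with the same replicate number share a mouse, a sort or a batch, so the block entered no main result. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No sample was left out.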

Results

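Gene expression was measured in marginal zone B cells of wild-type and Trpm5-/- mice after 4 h without stimulus, with LPS or with anti-IgM. LPS acts through Toll-like receptor 4, and anti-IgM cross-links the B cell receptor. TRPM5 is a calcium-activated channel for monovalent cations, and the series asks what its loss changes in B cells stimulated in these ways. Each of the 6 groups held 2 libraries. The Y-linked RNA helicase gene Ddx3y stood at 38.55 to 55.45 FPKM in all 12 libraries, and Xist, the RNA of the inactive X chromosome, at no more than 0.02459 FPKM. Libraries with LPS summed to higher FPKM than the others, up to 805373 against a lowest sum of 563461, and had fewer symbols above 0.

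Trpm5 (chromosome 7, 143069153 to 143094642, minus strand, mm10) was barely expressed and was left out of the tests by the filter on low values. In wild-type cells it read 0.0196 and 0.210 FPKM without stimulus, 0.434 and 0.321 FPKM with LPS, and 0.0590 and 0.0241 FPKM with anti-IgM. Trpm5-/- cells read 0.0236 and 0.0184 FPKM without stimulus, 0 and 0.0303 FPKM with LPS, and were listed at 0 in both libraries with anti-IgM. Divided by the size of a 1-fragment step, and within 0.05 of a whole number in each library, the values came to 40 fragments in the 6 wild-type libraries and 3 in the 6 Trpm5-/- libraries. Which part of the gene is deleted is not given in the sources used here, so fragments from the remaining exons cannot be separated from background.

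Under LPS, 388 of 10797 tested genes were called different between Trpm5-/- and wild-type cells. The test recovered 37.3% of simulated 1.5-fold changes here, so many smaller differences can be missed. Among the called genes with the largest rises were Lrmp, an endoplasmic reticulum membrane protein of lymphocytes, Il5ra, the receptor subunit for interleukin 5, and Plxnd1, a plexin receptor for semaphorins. Cd9, a tetraspanin abundant on marginal zone B cells, also rose. Fcer2a, the low-affinity IgE receptor CD23, fell, as did the immediate early transcription factor gene Egr1 and Icosl, a ligand for T cell costimulation. Lrmp went from 10.6 ± 2.39 to 43.6 ± 0.927 FPKM, Il5ra from 4.55 ± 0.0961 to 19.4 ± 0.162 FPKM, Cd9 from 246 ± 6.09 to 439 ± 26.1 FPKM and Egr1 from 62.7 ± 0.547 to 33.8 ± 1.33 FPKM (mean ± SD, n = 2 each).

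Of the cytokine genes Il6, Cxcl10 and Il10, only Il10 passed the test between genotypes under LPS. Il6 (chromosome 5, 30013114 to 30019981) averaged 54.2 ± 1.36 FPKM in wild-type and 88.8 ± 8.29 FPKM in Trpm5-/- cells (SD, n = 2). The log2 difference of 0.70 ± 0.19 was not called, with a limma adjusted p of 0.0864 and a range of 0.0534 to 0.361 over the alternatives. Cxcl10, a chemokine gene induced by interferons, averaged 93.8 ± 8.57 and 150 ± 18.1 FPKM (SD, n = 2), and its log2 difference of 0.67 ± 0.39 was not called either (limma adjusted p = 0.433, range 0.133 to 0.70). Il10, an anti-inflammatory cytokine of B cells, rose by 0.75 ± 0.16 (limma adjusted p = 0.0303, range 0.0117 to 0.226), from 18.3 ± 1.98 to 31.9 ± 7.75 FPKM (SD, n = 2). Il10 lost its call without wild-type LPS replicate 1 (adjusted p = 0.081) or 2 (0.18) and without Trpm5-/- LPS replicate 1 (0.16). Of the 20 tested cytokines and chemokines, 3 rose and 2 fell (with quantile normalization 1 and 1), or 6 and 2 adjusted over the list alone, and camera did not call the list (adjusted p = 0.0717). Ccl4 rose by 0.52 ± 0.07 and Ccl3, like it a chemokine that attracts monocytes and T cells, by 0.36 ± 0.07. Ltb, the membrane lymphotoxin, fell by 0.69 ± 0.07, and Il16 changed by -0.38 ± 0.09. The plot of Trpm5 and cytokine levels shows these libraries one by one.

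**Figure D1:**
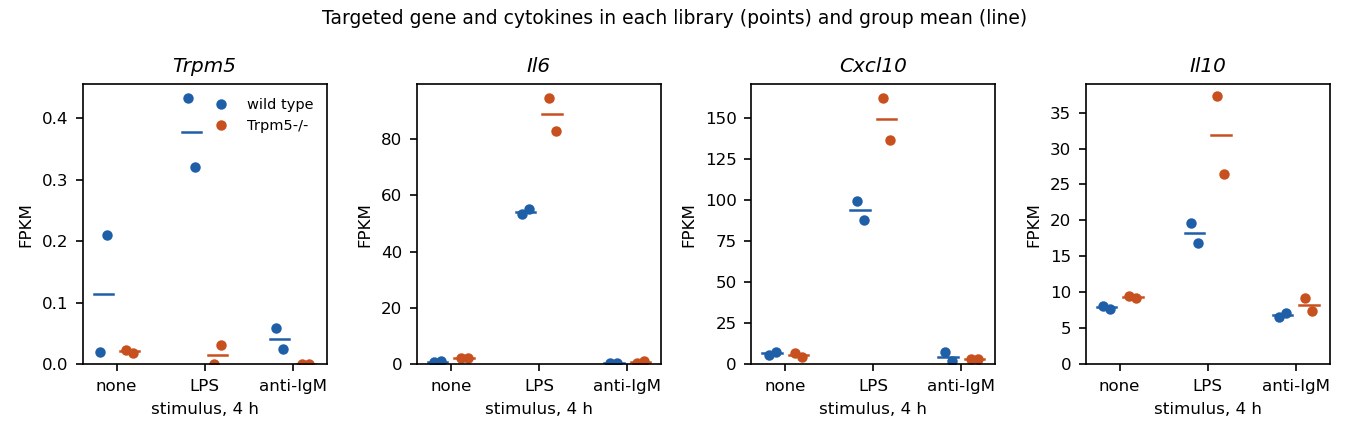
FPKM of Trpm5, Il6, Cxcl10 and Il10 in each library (points) with the group mean (line), for wild-type and Trpm5-/- cells without stimulus, with LPS or with anti-IgM for 4 h; with 2 libraries per group no error bars are drawn. Both Trpm5-/- LPS libraries lie above both wild-type LPS libraries for Il6 (94.7 and 83.0 against 53.3 and 55.2 FPKM) and for Cxcl10, differences that did not pass the test, and for Il10, which did; Trpm5 stayed below 0.5 FPKM in every library.

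Among groups of genes under LPS, the list of marginal zone identity was higher and that of follicular identity lower in Trpm5-/- cells, with a minority of members called. In the marginal zone list 5 of 19 tested genes rose and none fell, 5 and 1 adjusted over the list alone (camera adjusted p = 9.84e-05, and adjusted p = 0.0312 with an estimated correlation). Cd9 rose by 0.83 ± 0.06, Plxnd1 by 1.96 ± 0.16, the scavenger receptor gene Cd36 by 0.59 ± 0.06 and Dtx1, a target and regulator of Notch, by 0.63 ± 0.09. Of 13 follicular genes 3 fell, 5 adjusted over the list alone (camera adjusted p = 8.97e-06, but adjusted p = 0.0632 with an estimated correlation). They included Fcer2a at -0.74 ± 0.08 and the Fc receptor-like gene Fcrl1 at -0.54 ± 0.06. Pan-B markers, a group of genes shared by all B cells, fell in 7 of 11 cases, 9 with 1 rise adjusted over the list alone (camera adjusted p = 2.55e-07, and adjusted p = 0.0312 with an estimated correlation). Ms4a1 (CD20) stood at -0.34 ± 0.05 and Cd79b, a signalling chain of the B cell receptor, at -0.39 ± 0.05. Genes of B cell receptor signalling fell in 6 of 27 cases, 9 with 4 rises adjusted over the list alone (camera adjusted p = 0.000743, but adjusted p = 0.0849 with an estimated correlation).

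Mitosis genes rose in 3 of 18 cases under LPS, 8 adjusted over the list alone (camera adjusted p = 9.68e-06, and adjusted p = 0.0312 with an estimated correlation). Aurkb, a mitotic kinase, rose by 0.93 ± 0.16 and Top2a, which untangles DNA, by 0.65 ± 0.13. In the ribosome biogenesis list 2 of 28 genes rose over all genes and adjusted over the list alone (camera adjusted p = 8.97e-06, and adjusted p = 0.0312 with an estimated correlation). They were Odc1, for polyamine synthesis, at 0.36 ± 0.06 and Nob1. Immediate early genes fell in 6 of 25 cases, 8 adjusted over the list alone (camera adjusted p = 0.00622, but adjusted p = 0.0849 with an estimated correlation). They included Egr1 at -0.87 ± 0.07, Fos at -0.67 ± 0.10 and the mRNA decay factor gene Zfp36 at -0.51 ± 0.07. In the TLR4 signalling list 2 of 27 genes fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0325, but adjusted p = 0.12 with an estimated correlation). The kinase-like Irak3, which dampens the receptor, stood at -0.66 ± 0.13 and Ly86 at -0.32 ± 0.07. No member of the lists of calcium channels and pumps (24 tested) or of the calcineurin-NFAT response (17 tested) was called under LPS by limma, over all genes or adjusted over the list alone, with camera adjusted p of 0.523 and 0.632. The NFAT list had a median of 0.00743, a mean of 0.0032 and a test direction of down, and quantile normalization turned its median to -0.01658. Of 27 NF-kB targets 1 rose, the inhibitor gene Nfkbie, or 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.855, direction down with a median of 0.0103 that quantile normalization turned to -0.02963). With quantile normalization no target rose and 1 fell. Markers of erythroid cells fell in 2 of 10 cases, 4 adjusted over the list alone (camera adjusted p = 0.000743, and adjusted p = 0.0417 with an estimated correlation). These were the heme synthesis gene Alas2 at -0.57 ± 0.12 and the anion exchanger gene Slc4a1 at -0.73 ± 0.13. Macrophage markers rose in 2 of 10 cases, 1 with quantile normalization and 3 with 1 fall adjusted over the list alone (camera adjusted p = 0.412).

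In all, 196 genes were higher and 192 lower in Trpm5-/- than in wild-type cells under LPS (limma, 388 of 10797 tested, 1801 at an unadjusted p under 0.05), and 30 and 28 of them differed at least 2-fold. With quantile normalization the split was 117 and 188. Large rises outside the lists included the long noncoding RNA AI506816 at 2.12 ± 0.21, the ribosomal protein gene copy Rps4l at 1.97, Mid1, a ubiquitin ligase on microtubules, at 1.42 and the ciliary transport gene Ift140 at 1.25. Large falls included Prelid2, a lipid transfer protein of mitochondria, at -2.19 ± 0.19, the tRNA deaminase gene Adat2 at -1.94 and the lectin gene Clec2d at -1.82. The neighbouring gene BC064078 stood at -2.39, Crisp3, a secreted protein, at -1.44 and the lipid flippase gene Atp10d at -1.37. GENCODE M21 lists Atp10d as a polymorphic pseudogene. Amd1 and Amd2, near-identical copies of the gene for an enzyme of polyamine synthesis, moved in opposite ways, Amd1 by 1.98 ± 0.42 and Amd2 by -3.90 ± 0.36, so the share of each copy is uncertain. The small RNA genes Snord33 (1124 and 2893 FPKM) and Mir324 (386 and 497 FPKM) were listed at 0 in every library outside the Trpm5-/- LPS group, and Mir671 in both of its libraries.

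The count under LPS dropped to 183 and 158 without wild-type LPS replicate 1 and 2 and to 205 and 206 without Trpm5-/- LPS replicate 1 and 2, and to 21 in a fit of the 4 compared libraries alone. Of 71 genes named here by rule and called, 30 and 33 lost the call without those wild-type replicates and 28 and 28 without those Trpm5-/- replicates. Lrmp, Il5ra, Plxnd1, Cd9, Fcer2a, Egr1, Ltb, Prelid2, Adat2, Atp10d, BC064078, Snord33 and Mir324 were among those that kept their calls under every alternative run.

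With anti-IgM, the chemokine genes Ccl3 and Ccl4 rose more than 2-fold in Trpm5-/- cells, Ccl3 from 65.3 ± 0.135 to 140 ± 7.39 FPKM and Ccl4 from 329 ± 4.12 to 675 ± 21.4 FPKM (SD, n = 2). Il5ra rose from 0.333 ± 0.258 to 6.38 ± 1.37 FPKM, and Hs3st1, which modifies heparan sulfate, from 5.36 ± 1.09 to 24.6 ± 1.82 FPKM. Itpr2, a receptor that releases calcium from the endoplasmic reticulum, fell from 8.05 ± 0.452 to 3.23 ± 0.204 FPKM. Targets of NF-kB and genes of B cell receptor signalling were lower as groups. Both lists were already lower without stimulus (camera adjusted p = 0.00101 and 0.0352, but 0.106 and 0.231 with an estimated correlation). For the interaction with anti-IgM camera did not call NF-kB targets (adjusted p = 0.101). It called B cell receptor signalling (0.00369, but 0.201 with an estimated correlation). The comparison of genotypes with anti-IgM asks whether loss of TRPM5 also matters after cross-linking of the B cell receptor.

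Of the 27 NF-kB targets 10 fell with anti-IgM and 1 rose, 13 and 1 adjusted over the list alone (camera adjusted p = 4.96e-06, and adjusted p = 0.0465 with an estimated correlation). They included the survival gene Bcl2l1 at -0.55 ± 0.06, the adhesion molecule gene Icam1 at -0.59 ± 0.07, Nfkb2 at -0.35 ± 0.05 and Tnfaip3 (A20), which ends NF-kB signals, at -0.37 ± 0.06. In the B cell receptor list 6 of 27 fell, 12 adjusted over the list alone (camera adjusted p = 1.47e-06, and adjusted p = 0.0465 with an estimated correlation). Ptpn6 (SHP-1), a phosphatase that restrains the receptor, stood at -0.46 ± 0.05 and Cd72, an inhibitory surface receptor, at -0.42 ± 0.05. Follicular genes fell in 6 of 13 cases, over all genes and adjusted over the list alone (camera adjusted p = 9.8e-07, and adjusted p = 0.0465 with an estimated correlation). Fcer2a fell by 1.07 ± 0.08. Marginal zone genes rose in 3 of 19 cases, 5 with 1 fall adjusted over the list alone, and camera did not call the list (adjusted p = 0.0551). Of 11 pan-B markers 5 fell, 6 adjusted over the list alone (camera adjusted p = 7.4e-07, and adjusted p = 0.0465 with an estimated correlation). Of 18 mitosis genes 2 rose, 11 adjusted over the list alone (camera adjusted p = 1.49e-07, and adjusted p = 0.0237 with an estimated correlation). They were Top2a at 0.84 ± 0.13 and the survivin gene Birc5 at 0.62 ± 0.11. The plasma cell programme had 2 rises among 16 genes, 4 with 1 fall adjusted over the list alone (camera adjusted p = 0.00278, and adjusted p = 0.0465 with an estimated correlation). Jchain, which joins IgM pentamers, rose by 1.14 ± 0.18 and the chaperone gene Mzb1 by 0.36 ± 0.06. Among 24 calcium channels and pumps 2 fell, or 4 fell and 1 rose adjusted over the list alone, and camera did not call the list (adjusted p = 0.154). The 2 were Itpr2 at -1.10 ± 0.13 and Itpr1 at -0.68 ± 0.15. The calcineurin-NFAT list had no called member among 17 by limma, over all genes or adjusted over the list alone (camera adjusted p = 0.80), and a median of 0.0143 whose sign quantile normalization turned. Erythroid markers fell in 1 of 10 cases, Alas2, or 5 with 1 rise adjusted over the list alone (camera adjusted p = 0.0164, but adjusted p = 0.0743 with an estimated correlation). Macrophage markers rose in 2 of 10 cases, over all genes and adjusted over the list alone (camera adjusted p = 0.175), Hmox1 at 0.88 ± 0.11 and the lysozyme gene Lyz2 at 0.92 ± 0.17, and the stromal marker Pecam1 fell by 0.52 ± 0.11. Malat1 and Neat1 stood at -0.40 ± 0.10 and -0.39 ± 0.10 (limma adjusted p = 0.0506 and 0.0674). Both fell adjusted over the list alone and with quantile normalization.

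With anti-IgM 206 genes were higher and 207 lower in Trpm5-/- cells (limma, 413 of 10797 tested, 2116 at an unadjusted p under 0.05), 29 and 33 of them at least 2-fold. Il5ra at 2.47 ± 0.20, AI506816 at 2.31, the sulfotransferase gene Sult2b1 at 2.09, Hs3st1 at 2.02, Rps4l at 1.57, Spry1, an inhibitor of growth factor signalling, at 1.45 and the peroxisomal Nudt7 at 1.43 led the rises. Prelid2 at -2.38, the kinase gene Stk38l at -1.84, the actin-related gene Actr3b at -1.57, Crisp3 at -1.51 and Adat2 at -1.41 led the falls. The small RNA gene Scarna13 stood at -1.77, and Snora43 (47.8 and 117 FPKM in wild-type cells) was listed at 0 in both Trpm5-/- libraries. The kallikrein gene Klk1b22, a member of a family of near-identical copies, was listed at 0 in both Trpm5-/- libraries. Mir18 (235 and 577 FPKM in wild-type cells with anti-IgM) was listed at 0 in every other library. The count became 156 and 119 without wild-type anti-IgM replicate 1 and 2, 142 and 129 without Trpm5-/- anti-IgM replicate 1 and 2, and 116 in a fit of the compared libraries alone. Of 72 genes named by rule and called, 35 and 40 lost the call without those wild-type replicates and 37 and 38 without those Trpm5-/- replicates, while Ccl3, Ccl4, Il5ra, Fcer2a, Cd9, Itpr2, Ptpn6, Cd72 and Nfkb2 were among the 24 that kept it under every alternative.

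Without stimulus, the baseline comparison, Trpm5-/- cells had more RNA for Spib, a B cell transcription factor of the ETS family (49.4 ± 0.0665 to 133 ± 7.46 FPKM), for Cd9 (276 ± 11 to 471 ± 1.29 FPKM) and for Il5ra (1.07 ± 0.324 to 10.9 ± 2.05 FPKM; SD, n = 2). Itpr2 fell from 16.2 ± 0.81 to 8.29 ± 0.208 FPKM. The ribosome biogenesis and mitosis lists had medians of 0.2612 and 0.6656. The ubiquitous reference list stood at 0.1226, with 3 rises (camera adjusted p = 0.00116, but adjusted p = 0.231 with an estimated correlation). In the ribosome biogenesis list 13 of 28 genes rose, 25 adjusted over the list alone (camera adjusted p = 1.91e-15, and adjusted p = 0.00426 with an estimated correlation). Odc1 stood at 0.50 ± 0.06, the rRNA processing gene Rrp12 at 0.47 ± 0.06 and the spermidine synthase gene Srm at 0.37 ± 0.06. Of 18 mitosis genes 9 rose, 16 adjusted over the list alone (camera adjusted p = 2.47e-11, and adjusted p = 0.00426 with an estimated correlation). The cyclin genes Ccnb1 and Ccnb2 rose by 0.84 ± 0.16 and 0.79 ± 0.14, and the motor protein gene Kif11 by 0.93 ± 0.18. The unfolded protein response had 7 rises among 22 genes, 12 with 1 fall adjusted over the list alone (camera adjusted p = 5.69e-05, and adjusted p = 0.0235 with an estimated correlation). The protein folding gene Pdia6 rose by 0.52 ± 0.05 and the chaperone gene Hspa5 by 0.36 ± 0.05. Of 27 genes of cell cycle entry 5 rose, 13 with 1 fall adjusted over the list alone (camera adjusted p = 4.78e-05, and adjusted p = 0.0389 with an estimated correlation). Of 19 glycolysis genes 8 rose, 5 with quantile normalization and 10 adjusted over the list alone (camera adjusted p = 0.000103, and adjusted p = 0.036 with an estimated correlation).

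Follicular genes fell in 5 of 13 cases without stimulus, 6 adjusted over the list alone (camera adjusted p = 7.56e-08, and adjusted p = 0.0389 with an estimated correlation), with Satb1, a chromatin organizer, at -0.51 ± 0.06. Marginal zone genes rose in 4 of 19 cases, 6 adjusted over the list alone (camera adjusted p = 0.00283, but adjusted p = 0.0552 with an estimated correlation). Calcium channels and pumps had 2 falls among 24 genes, over all genes and adjusted over the list alone (camera adjusted p = 0.0486, but adjusted p = 0.20 with an estimated correlation). Itpr2 fell by 0.89 ± 0.13 and Itpr1 by 0.93 ± 0.15. Pan-B markers had 3 falls (camera adjusted p = 0.000103, but adjusted p = 0.0552 with an estimated correlation). NF-kB targets had 1 rise and 4 falls (0.00101, but 0.106). B cell receptor signalling had 1 rise and 1 fall (0.0352, but 0.231) and immediate early genes 2 rises and 6 falls (0.0075, but 0.12). The plasma cell programme had 5 rises and 1 fall, without a camera call (adjusted p = 0.095). Malat1 and Neat1, nuclear RNAs taken as signs of RNA quality, were lower by -0.45 ± 0.10 and -0.42 ± 0.10 (limma adjusted p = 0.026 and 0.041) in the same libraries as these groups. In all, 481 genes were higher and 179 lower without stimulus (limma, 660 of 10797 tested, 2226 at an unadjusted p under 0.05), 30 and 40 of them at least 2-fold, and with quantile normalization the split was 442 and 277. AI506816 at 3.44, the glutathione transferase gene Mgst1 at 2.53, Hs3st1 at 2.24, Rps4l at 1.98, the zinc finger gene Zfp948 at 1.67 and Chac1, which degrades glutathione, at 1.46 were among the largest rises. Prelid2 at -2.42, Adat2 at -1.83, Clec2d at -1.61, the adaptor gene Dok2 at -1.33, Stk38l at -1.33, Isoc2b at -1.26 and the sterol transfer gene Gramd1a at -1.23 were among the largest falls, and Klk1b22 was listed at 0 in both Trpm5-/- libraries. The count fell to 274 and 245 without wild-type unstimulated replicate 1 and 2, to 159 and 218 without Trpm5-/- unstimulated replicate 1 and 2, and to 51 in a fit of the compared libraries alone. Of 88 genes named by rule and called, 35 and 38 lost the call without those wild-type replicates and 54 and 40 without those Trpm5-/- replicates. Spib, Cd9, Il5ra, Fcer2a, Ccl3 and Pdia6 were among the 18 that kept it under every alternative.

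Averaged over the 3 conditions, with 6 libraries of each genotype, differences had smaller standard errors, though an averaged call does not show a difference in each condition. The labels do not say whether the conditions used separate animals. If they shared animals, the gain in precision is partly repetition. Spib (chromosome 7, 44525993 to 44532071) rose by 1.08 ± 0.03 (limma adjusted p = 1.1e-07), Cd9 (chromosome 6, 125460266 to 125494791) by 0.75 ± 0.03 (1.2e-06), Il5ra (chromosome 6, 106710357 to 106749037) by 2.29 ± 0.11 (1.9e-06) and Ccl3 by 0.78 ± 0.04 (2.8e-06). Prelid2 (chromosome 18, 41875600 to 41951242) fell by 2.33 ± 0.11 (limma adjusted p = 1.6e-06) and Fcer2a by 0.82 ± 0.04 (3.3e-06). Il6 rose by 0.58 ± 0.11 (limma adjusted p = 0.0063, range 0.000876 to 0.0221 over the alternatives) and Il10 by 0.41 ± 0.09 (0.015, range 0.00415 to 0.0431). Cxcl10 was not called (limma adjusted p = 0.90, range 0.107 to 0.992). Hmox1, which degrades heme, rose by 0.90 ± 0.06 and Jchain by 0.93 ± 0.10.

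In the averaged fit marginal zone genes rose in 7 of 19 cases, over all genes and adjusted over the list alone (camera adjusted p = 0.000415, and adjusted p = 0.0322 with an estimated correlation). Cr2, the complement receptor CD21 that marks these cells, stood at -0.11 ± 0.04 (limma adjusted p = 0.10). Follicular genes fell in 7 of 13 cases, 9 adjusted over the list alone (camera adjusted p = 3.66e-08, and adjusted p = 0.0322 with an estimated correlation). Of 11 pan-B markers 9 fell, 9 with 1 rise adjusted over the list alone (camera adjusted p = 4.8e-08, and adjusted p = 0.0265 with an estimated correlation). The antigen presentation genes H2-Ab1 and Cd74 stood at -0.44 ± 0.03 and -0.41 ± 0.04. Of 18 mitosis genes 16 rose, 18 adjusted over the list alone (camera adjusted p = 3.68e-11, and adjusted p = 0.00623 with an estimated correlation), with Top2a at 0.76 ± 0.07. In the ribosome biogenesis list 19 of 28 rose, 12 with quantile normalization and 26 adjusted over the list alone (camera adjusted p = 1.43e-12, and adjusted p = 0.00623 with an estimated correlation), with Odc1 at 0.39 ± 0.04. Cell cycle entry had 13 rises and 1 fall among 27, 14 and 3 adjusted over the list alone (camera adjusted p = 5.02e-05, and adjusted p = 0.0322 with an estimated correlation), with the replication gene Pcna at 0.20 ± 0.03. Glycolysis had 10 rises and 2 falls among 19, 11 and 2 adjusted over the list alone (camera adjusted p = 0.000451, and adjusted p = 0.0322 with an estimated correlation). Slc16a1, a lactate transporter, stood at 0.41 ± 0.05. The unfolded protein response had 11 rises and 3 falls among 22, 16 and 3 adjusted over the list alone (camera adjusted p = 0.00014, and adjusted p = 0.0265 with an estimated correlation), with Pdia6 at 0.40 ± 0.03. B cell receptor signalling had 2 rises and 12 falls among 27, 3 and 14 adjusted over the list alone (camera adjusted p = 5.02e-05, and adjusted p = 0.049 with an estimated correlation). Ptpn6 stood at -0.28 ± 0.03 and Cd81, a tetraspanin whose gene lies beside Trpm5 on chromosome 7, at -0.37 ± 0.04. Erythroid markers fell in 4 of 10 cases, over all genes and adjusted over the list alone (camera adjusted p = 0.00185, and adjusted p = 0.037 with an estimated correlation). In the RNA quality list 2 of 3 tested genes fell, over all genes, Malat1 at -0.32 ± 0.06 and Neat1 at -0.20 ± 0.06, beside these groups.

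Other lists moved less, or lost their call with an estimated correlation. NF-kB targets had 1 rise and 10 falls among 27, 2 and 12 adjusted over the list alone (camera adjusted p = 0.000415, but adjusted p = 0.0716 with an estimated correlation). Immediate early genes had 5 rises and 10 falls among 25, 7 and 11 adjusted over the list alone (camera adjusted p = 0.0142, but adjusted p = 0.116 with an estimated correlation). Fos fell by 0.80 ± 0.06 and Egr1 by 0.68 ± 0.04. Activation surface proteins had 2 rises and 8 falls among 21, 3 and 8 adjusted over the list alone (camera adjusted p = 0.0295, but adjusted p = 0.104 with an estimated correlation). The plasma cell programme had 5 rises and 1 fall among 16, 6 and 2 adjusted over the list alone (camera adjusted p = 0.0459, but adjusted p = 0.11 with an estimated correlation). Oxidative phosphorylation had 6 rises among 22 (with quantile normalization 1 rise and 1 fall), 8 adjusted over the list alone (camera adjusted p = 0.00096, but adjusted p = 0.203 with an estimated correlation). The ubiquitous reference list had 4 rises among 16 (with quantile normalization 1), 5 adjusted over the list alone (camera adjusted p = 0.00154, but adjusted p = 0.203 with an estimated correlation), with a median of 0.0785. Calcium channels and pumps had 2 rises and 5 falls among 24, 3 and 5 adjusted over the list alone, without a camera call (adjusted p = 0.0959). The falls were Itpr2 at -0.70 ± 0.07, Itpr1 at -0.66 ± 0.09 and the store-operated channel gene Orai2 at -0.46 ± 0.10. The calcium pump gene Atp2a3 at -0.28 ± 0.07 and the potassium channel gene Kcna3 at -0.32 ± 0.09 fell as well. Itpr2 (146108299 to 146502223) and Itpr1 (108213096 to 108551109) lie on chromosome 6. Nearby are Stk38l (146724995) and Il5ra (106710357), whose large genotype differences are given below. The rises were Saraf, which limits store-operated entry, at 0.24 ± 0.07 and the calcium-activated potassium channel gene Kcnn4 at 0.39 ± 0.11.

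Camera called none of the remaining lists in the averaged fit. The calcineurin-NFAT list had 2 falls among 17, 2 rises and 2 falls adjusted over the list alone (adjusted p = 0.702; median -0.0537, mean 0.0101, test direction down). Cytokines and chemokines had 4 rises and 2 falls among 20, 7 and 2 adjusted over the list alone (adjusted p = 0.264). Interferon-stimulated genes had 4 falls among 29, the same adjusted over the list alone (adjusted p = 0.515; median 0.0302, mean -0.0496, test direction down), led by Ifi44 at -1.69 ± 0.20. TLR4 signalling had 2 rises and 3 falls among 27, 3 and 6 adjusted over the list alone (adjusted p = 0.141). Apoptosis regulators had 1 rise and 5 falls among 22, 2 and 6 adjusted over the list alone (adjusted p = 0.164). Macrophage and monocyte markers had 2 rises and 2 falls among 10, 3 and 2 adjusted over the list alone (adjusted p = 0.915; median -0.124, mean 0.0181, test direction up). The neighbours of Trpm5 on chromosome 7 had 2 rises and 4 falls among 24, 3 and 4 adjusted over the list alone (adjusted p = 0.616; median 0.0269, mean -0.0241, test direction down). Tspan32 (143005046 to 143019644) stood at -0.51 ± 0.05 and Cd81 (143052739 to 143067934) at -0.37 ± 0.04. Lists with fewer than 5 tested genes had no set test. None of 3 T cell, 1 NK cell, 2 neutrophil, 3 dendritic cell and 1 platelet markers was called by limma over all genes, though adjusted over the list alone 1 T cell and 1 neutrophil marker fell and dendritic markers had 1 rise and 1 fall. The 1 stromal or endothelial marker, Pecam1, fell by 0.24 ± 0.06, and of 4 sex-chromosome genes 1 fell, Eif2s3y at -0.24 ± 0.04. The plot of list medians by comparison sets these groups side by side.

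**Figure D2:**
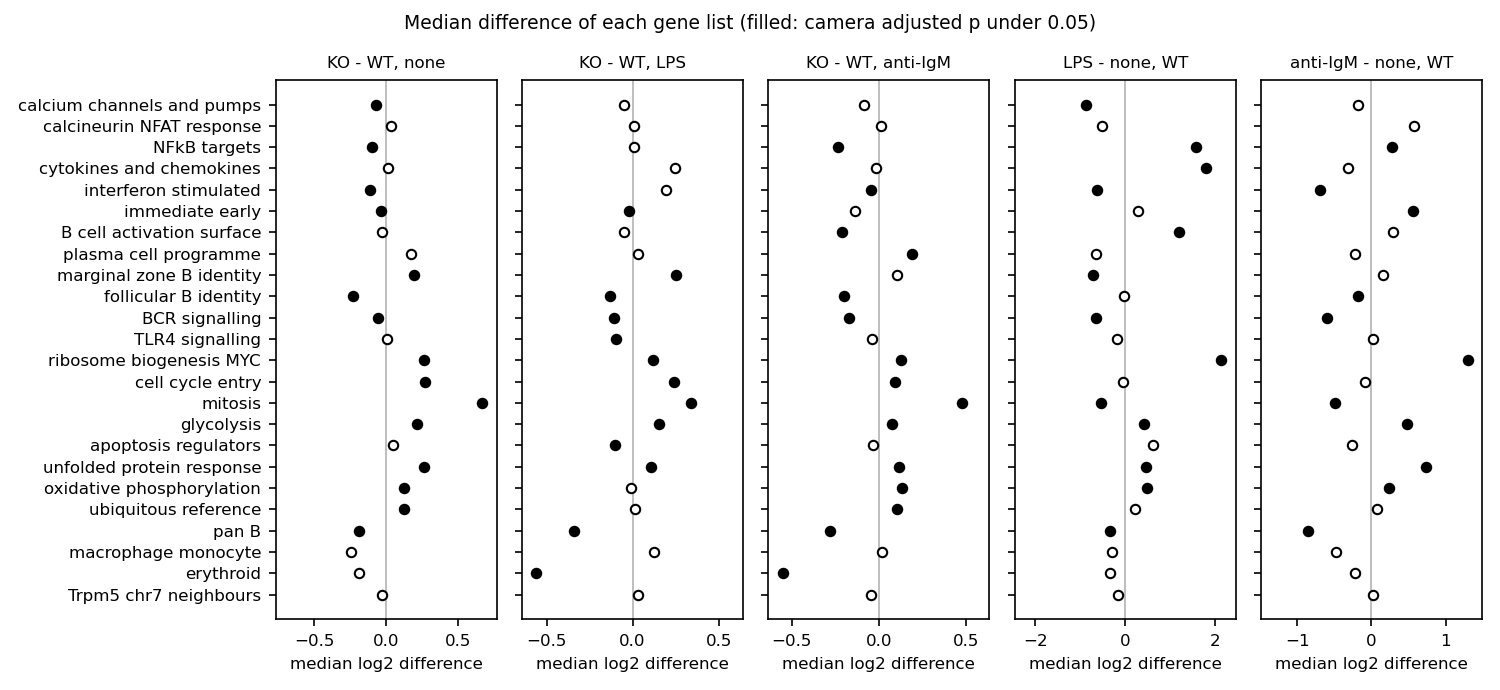
Median log2 difference of each list with at least 5 tested genes in 5 comparisons (KO, Trpm5-/-; WT, wild type); filled points have a camera adjusted p under 0.05 with the preset correlation, and each panel has its own axis. Mitosis and ribosome biogenesis lie to the right in all 3 genotype panels and the follicular and pan-B lists to the left. The ubiquitous reference list also lies to the right there, with medians of 0.1226 (unstimulated), 0.01362 (LPS) and 0.1025 (anti-IgM). Ribosome biogenesis stands at 0.1278 with anti-IgM. Quantile normalization turned the sign of the medians for the NFAT and NF-kB lists (genotype, LPS) and the TLR4 list (genotype, unstimulated). It also turned the NFAT, cytokine, glycolysis and ubiquitous lists (genotype, anti-IgM). For LPS in wild type it turned the cell cycle entry, oxidative phosphorylation, ubiquitous, macrophage and Trpm5 neighbour lists. For anti-IgM in wild type it turned the TLR4 and ubiquitous lists.

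The averaged difference passed the test for 1097 genes that were higher and 635 that were lower in Trpm5-/- cells (limma, 1732 of 10797 tested, 3222 at an unadjusted p under 0.05), with 24 and 27 of at least 2-fold. With quantile normalization the split was 786 and 730. Leaving out each library in turn gave 1301 to 1595 genes. Of 116 genes named by rule and called, 12 lost the call in some fit without 1 library, among them Ddx58, Hprt, Ikbkb, Ikzf3, Irf1, Neat1, Pecam1, Pik3ap1, Rsad2 and Vcam1. Other differences of at least 2-fold included Klk1b22, listed at 0 in all 6 Trpm5-/- libraries, AI506816 at 2.63 ± 0.12, the snoRNA host gene Snhg9 at 2.72, Sult2b1 at 1.88, Rps4l at 1.84, Hs3st1 at 1.81, Mgst1 at 1.75, Adat2 at -1.73, Clec2d at -1.55, Zfp948 at 1.42, Crisp3 at -1.27, Plxnd1 at 1.24, Stk38l at -1.21, Atp10d at -1.12, Actr3b at -1.12, the phospholipase-like gene Plbd1 at -1.07 and Crebl2 at -1.05. Called genes overlapped between conditions more than independent calls would. Of those higher, 97 were shared between the unstimulated and LPS comparisons (8.73 if calls were independent), 124 between unstimulated and anti-IgM (9.18) and 85 between LPS and anti-IgM (3.74). Of those lower, 62, 87 and 78 were shared (3.18, 3.43 and 3.68 if independent). The comparisons share each gene's estimated spread, so calls are not independent and these figures may be too low as a chance level. Across all tested genes, which are not independent replicates, the genotype differences had Pearson r = 0.105 (unstimulated and LPS), 0.248 (unstimulated and anti-IgM) and 0.19 (LPS and anti-IgM), with Spearman rho of 0.319, 0.43 and 0.304. In all 3 conditions 67 genes were higher and 44 lower.

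Of the 42 genes called and at least 2-fold different in the averaged fit, small RNA genes left out, 10 lay on chromosome 6, which holds 490 of 10584 tested genes with a position. Among these were Il5ra, Plxnd1, Clec2d, Mgst1, Stk38l and Rps4l. A further 5 lay on chromosome 7, among them Klk1b22, Spib and Sult2b1, and 0 of the 42 lay within 10 Mb of Trpm5. The plot of differences along chromosomes 6 and 7 shows these positions.

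**Figure D3:**
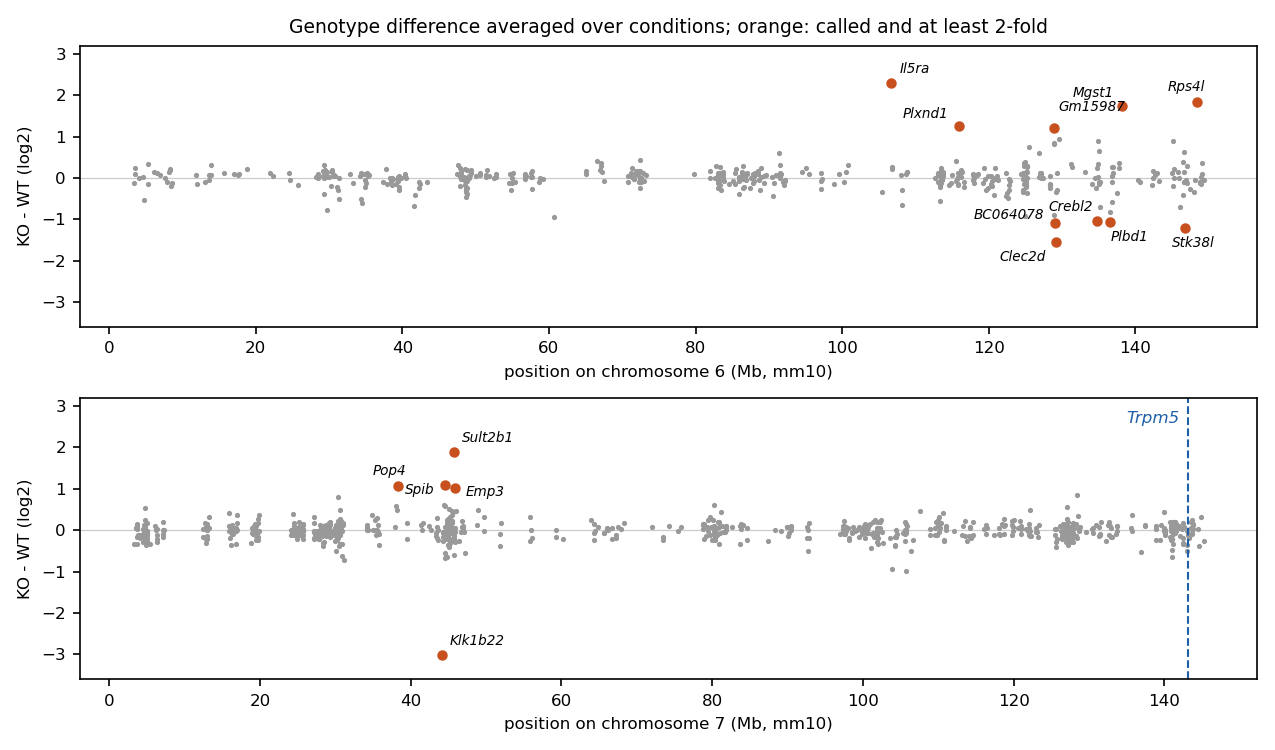
Averaged log2 difference (Trpm5-/- minus wild type) of each tested gene against its position in Mb on chromosomes 6 and 7 (mm10); orange points are called genes of at least 2-fold, and the dashed line marks Trpm5. On chromosome 6 the 10 orange points lie beyond 100 Mb, and on chromosome 7 the 5 orange points lie between 38 and 46 Mb, away from Trpm5.

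LPS changed most of the expressed genes in wild-type cells. Il6 went from 0.916 ± 0.112 to 54.2 ± 1.36 FPKM, Bcl2l1 from 10.9 ± 0.311 to 231 ± 0.605 FPKM and Nfkbiz, an inducible partner of NF-kB, from 14.4 ± 0.0128 to 326 ± 16.0 FPKM (SD, n = 2). The proto-oncogene Myc rose from 57.6 ± 1.73 to 480 ± 7.43 FPKM. S1pr1, the receptor that places these cells in the marginal zone, fell from 185 ± 1.11 to 9.25 ± 2.5 FPKM, and Susd3 from 107 ± 5.38 to 4.6 ± 1.34 FPKM. All 28 genes of the ribosome biogenesis list rose, over all genes and adjusted over the list alone, with a median of 2.14 (camera adjusted p = 2.7e-16, and adjusted p = 0.00608 with an estimated correlation). In the NF-kB list 25 of 27 NF-kB targets rose, the same adjusted over the list alone (camera adjusted p = 6.03e-10, and adjusted p = 0.0361 with an estimated correlation).

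Other large rises were Mir155hg, the host of miR-155, at 4.16, Il2ra, the interleukin 2 receptor alpha chain, at 4.10, the chemokine genes Ccl22 at 3.83 and Cxcl10 at 3.64, and Il1b at 3.65. Il10 rose by 1.11 and Ccl3 by 2.46. Besides S1pr1 and Susd3, the transcription factor gene Hhex at -4.25, the RNA Neat1 at -4.20, the glycosyltransferase gene B3gnt8 at -4.05, Fcrla at -4.01, Acp5 at -3.95 and the integrin gene Itgb7 at -3.94 fell most. Of 20 cytokines and chemokines 13 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.0168, but adjusted p = 0.0746 with an estimated correlation). Activation surface proteins rose in 15 and fell in 3 of 21 cases, the same adjusted over the list alone (camera adjusted p = 0.000409, but adjusted p = 0.0518 with an estimated correlation). Calcium channels and pumps fell in 20 of 24 cases and rose in 2, the same adjusted over the list alone (camera adjusted p = 0.000856, but adjusted p = 0.0746 with an estimated correlation). The channel gene Trpv2 fell by 2.10 ± 0.12, Itpr2 by 1.90 ± 0.13 and the calcium sensor gene Stim1 by 1.57 ± 0.13. Atp2a2, a pump that refills the endoplasmic reticulum, was 1 of the 2 that rose. B cell receptor signalling fell in 20 of 27 cases and rose in 4, the same adjusted over the list alone (camera adjusted p = 0.000298, but adjusted p = 0.0746 with an estimated correlation). The inhibitory adaptor gene Dok3 fell by 3.78 ± 0.07. Mitosis genes fell in 12 of 18 cases, the same adjusted over the list alone (camera adjusted p = 0.0127, but adjusted p = 0.0746 with an estimated correlation). Oxidative phosphorylation had 16 rises and 3 falls among 22, the same adjusted over the list alone (camera adjusted p = 0.00315, but adjusted p = 0.263 with an estimated correlation), but quantile normalization turned its median from 0.485 to -0.07449, with 6 rises and 9 falls. Beside these groups 2 of 3 RNA quality genes fell in each genotype, over all genes and adjusted over the list alone, Malat1 at -1.12 ± 0.10 and Neat1 at -4.20 ± 0.10 in wild-type cells, and at -0.79 ± 0.10 and -3.57 ± 0.10 in Trpm5-/- cells. Erythroid markers fell in 4 of 10 cases in wild-type (3 adjusted over the list alone) and 5 in Trpm5-/- cells (5), without a camera call (adjusted p = 0.275 and 0.101). Of 3 dendritic markers 2 rose in each genotype, over all genes and adjusted over the list alone, Zbtb46 at 3.10 ± 0.12 and Flt3 at 1.48 ± 0.15 in wild-type and 3.26 ± 0.12 and 1.56 ± 0.15 in Trpm5-/- cells. Macrophage markers had 2 rises and 2 falls among 10 in wild-type cells, the same adjusted over the list alone (camera adjusted p = 0.659), with a median of -0.291 that quantile normalization turned to 0.06286. In Trpm5-/- cells they had 2 rises and 1 fall, the same adjusted over the list alone (camera adjusted p = 0.844), with a median of -0.0224 against a mean of 0.199 and a test direction of up, and quantile normalization turned the median to 0.3009. Prf1, Itgb3 and Pecam1, the tested markers of NK cells, platelets and stroma, fell in each genotype, with -0.97 ± 0.25, -2.37 ± 0.30 and -1.72 ± 0.11 in wild-type cells.

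In wild-type cells 3774 genes rose and 3715 fell with LPS (limma, 7489 of 10797, 7758 at an unadjusted p under 0.05), 1414 and 1669 at least 2-fold. In Trpm5-/- cells 3759 rose and 3654 fell (7413; 7686 unadjusted), 1378 and 1674 at least 2-fold, led by Il6 at 4.83, Cxcl10 at 4.54, Bcl2l1 at 4.47, Ccl22 at 4.38, Nfkbiz at 4.27 and Mir155hg at 4.18. Il10 rose by 1.64. The ribonuclease gene Rnase6 at -4.42, Susd3 at -4.57, Hhex at -4.21, Ccng2, a cyclin of resting cells, at -4.18, the acetate-using enzyme gene Acss1 at -3.94 and AB124611 at -3.93 fell most. In Trpm5-/- cells, as in wild-type cells, all 28 ribosome biogenesis genes rose (28 adjusted over the list alone; camera adjusted p = 3.95e-16, and adjusted p = 0.00625 with an estimated correlation). Again 25 of 27 NF-kB targets rose, 26 adjusted over the list alone (camera adjusted p = 2.93e-11, and adjusted p = 0.0262 with an estimated correlation). Of the genes that rose, 3434 were shared by both genotypes (1310 if calls were independent, which they are not), and of those that fell, 3200 (1260). Across genes, which are not independent replicates, the responses of both genotypes had Pearson r = 0.868 and Spearman rho = 0.936. With genes of a mean of at least 5 FPKM only, the median response of all genes was 0.138 in wild-type and 0.125 in Trpm5-/- cells, against -0.0177 and -0.0183 for all tested genes.

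**Figure D4:**
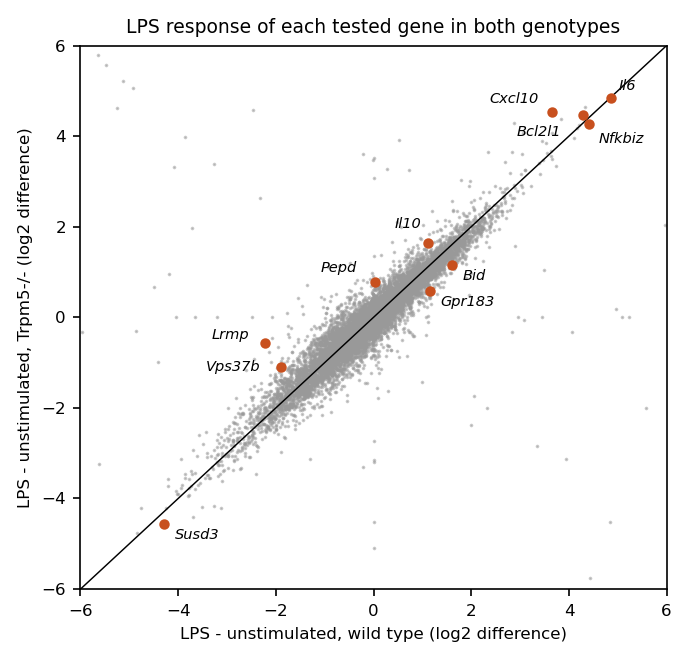
Log2 response to LPS of each tested gene in wild-type (x axis) and Trpm5-/- cells (y axis), each the difference of 2 libraries and 2; the line marks equal responses, orange points are named genes, and points beyond the axes, such as Snord33, are not drawn. Most genes follow the line; Lrmp, Vps37b and Pepd lie above it and Bid and Gpr183 below it, and their interaction was called, while Il6, Cxcl10 and Il10 were not called for interaction.

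The interaction asks whether the response to LPS itself differed between genotypes. It does not separate the loss of TRPM5 from other differences between the mice. Lrmp (chromosome 6, 145115653 to 145174934) fell with LPS in wild-type cells from 52.1 ± 1.55 to 10.6 ± 2.39 FPKM but went from 64.8 ± 2.07 to 43.6 ± 0.927 FPKM in Trpm5-/- cells (SD, n = 2), a difference of responses of 1.65 ± 0.15 (limma adjusted p = 0.0031, called under every alternative, range 3.56e-05 to 0.0356). The endosomal sorting gene Vps37b (0.81 ± 0.11, limma adjusted p = 0.033, range 0.0194 to 0.157) and the dipeptidase gene Pepd (0.74 ± 0.10, 0.034, range 0.0144 to 0.142) also had higher responses in Trpm5-/- cells. Gpr183, the oxysterol receptor that guides B cells in the spleen (-0.58 ± 0.08, limma adjusted p = 0.04, range 0.0261 to 0.195), the cell death gene Bid (-0.46 ± 0.06, 0.034, range 0.0223 to 0.173) and Amd2 (-3.80 ± 0.51, 0.033, range 0.00535 to 0.148) had lower ones. Gpr183 reached 142 ± 8.28 FPKM with LPS in wild-type and 84.8 ± 0.735 FPKM in Trpm5-/- cells, and Pepd 44.2 ± 4.59 and 79.9 ± 0.477 FPKM. The other called genes were Klk1b22 and the small RNA genes Snord33, Mir324, Snora31 and Snord16a, each listed at 0 in both libraries of at least 1 group. Il6 had an interaction of -0.02 (limma adjusted p = 0.992, range 0.814 to 1), Cxcl10 of 0.89 (0.616, range 0.425 to 0.797) and Il10 of 0.53 (0.461, range 0.29 to 0.727), none called.

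In all, 7 interactions with LPS were positive and 4 negative (limma, 11 of 10797, 1113 at an unadjusted p under 0.05). Of the 11 genes, 7 lost their calls without the filter on low values and 5 with replicate number as a block. Camera called 9 lists for this interaction, each lost with an estimated correlation (adjusted p of 0.105 to 0.343), among them interferon-stimulated genes with a mean of 0.27 (camera adjusted p = 0.00079, but adjusted p = 0.343 with an estimated correlation). Ribosome biogenesis had a mean of -0.14 (camera adjusted p = 1.78e-05, but adjusted p = 0.105 with an estimated correlation). The count was 8 and 3 without wild-type unstimulated replicate 1 and 2, 5 and 5 without Trpm5-/- unstimulated replicate 1 and 2, 6 and 6 without wild-type LPS replicate 1 and 2, and 23 and 7 without Trpm5-/- LPS replicate 1 and 2, and 5 in a fit of the compared libraries alone. The genes other than Lrmp, Snord33 and Mir324 lost their calls in some of these fits: 6 and 8 of the 11 without the wild-type unstimulated replicates, 7 and 7 without the Trpm5-/- unstimulated ones, 5 and 6 without the wild-type LPS ones and 3 and 5 without the Trpm5-/- LPS ones.

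Anti-IgM changed fewer genes than LPS. In wild-type cells Egr2, a transcription factor gene induced by calcium and NFAT, went from 24.1 ± 1.34 to 163 ± 9.68 FPKM, and Gfi1, a transcriptional repressor, from 3.76 ± 0.543 to 35.4 ± 1.66 FPKM (SD, n = 2). Rasgrp2, an activator of integrin signalling, fell from 43.8 ± 0.79 to 2.94 ± 0.647 FPKM. All 28 ribosome biogenesis genes rose, over all genes and adjusted over the list alone (camera adjusted p = 7.72e-20, and adjusted p = 0.00349 with an estimated correlation). In all 18 of 22 genes of the unfolded protein response rose, 19 with 1 fall adjusted over the list alone (camera adjusted p = 1.26e-06, and adjusted p = 0.0132 with an estimated correlation). Immediate early genes rose in 14 and fell in 4 of 25 cases, 15 and 4 adjusted over the list alone (camera adjusted p = 0.00947, but adjusted p = 0.197 with an estimated correlation). NF-kB targets rose in 15 and fell in 4 of 27 cases, the same adjusted over the list alone (camera adjusted p = 0.00947, but adjusted p = 0.207 with an estimated correlation). Of 29 interferon-stimulated genes 17 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 1.6e-05, but adjusted p = 0.26 with an estimated correlation). B cell receptor signalling had 6 rises and 17 falls among 27, 6 and 18 adjusted over the list alone (camera adjusted p = 0.000406, but adjusted p = 0.141 with an estimated correlation). In the calcineurin-NFAT list 9 genes rose and 3 fell of 17, the same adjusted over the list alone, without a camera call in wild-type cells (adjusted p = 0.0746).

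The G protein regulator gene Rgs1 at 2.70, Snhg9 at 2.64, the xenobiotic receptor gene Ahr at 2.48 and Mreg at 2.40 were also among the largest rises with anti-IgM. Icosl at -3.27, Itgb7 at -3.22, Rasa3, a brake on Ras, at -3.04, B3gnt8 at -2.94, the phosphodiesterase gene Pde2a at -2.94, S100a6 at -2.85, Il10ra at -2.83 and Ltb at -2.70 fell. In wild-type cells 2991 genes rose and 2255 fell (limma, 5246 of 10797, 5946 at an unadjusted p under 0.05), 544 and 636 at least 2-fold. In Trpm5-/- cells 2899 rose and 2487 fell (5386; 6076 unadjusted), 440 and 672 at least 2-fold. There Egr2 at 2.66, Gfi1 at 2.51, Mreg at 2.43, Gng4 at 2.35, Rgs1 at 2.29 and Tagap at 2.19 rose, and Icosl at -3.65, Rasgrp2 at -3.31, Itgb7 at -3.15, Acp5 at -3.09, Hepacam2 at -3.09 and B3gnt8 at -3.08 fell. Of 22 genes of the unfolded protein response 15 rose and 2 fell in Trpm5-/- cells, the same adjusted over the list alone (camera adjusted p = 2.87e-05, and adjusted p = 0.0251 with an estimated correlation). In the calcineurin-NFAT list 10 rose and 4 fell there, the same adjusted over the list alone (camera adjusted p = 0.0441, but adjusted p = 0.167 with an estimated correlation). Beside these groups Malat1 fell by 0.67 ± 0.10 in wild-type and 0.63 ± 0.10 in Trpm5-/- cells, and erythroid markers fell in 1 and 5 of 10 cases (0 and 5 adjusted over the list alone), without a camera call (adjusted p = 0.202 and 0.105). Of 3 dendritic markers 2 rose in each genotype, over all genes and adjusted over the list alone. Macrophage markers had 1 rise and 3 falls among 10 in wild-type cells, 1 and 4 adjusted over the list alone (camera adjusted p = 0.108). The platelet marker Itgb3 and the stromal marker Pecam1 fell in each genotype. One T cell marker (1 call) rose in each genotype, and 1 neutrophil marker fell in wild-type cells, though not with quantile normalization. Both genotypes shared 2487 rises and 1836 falls (803 and 519 if calls were independent, which they are not). Across genes the responses had Pearson r = 0.73 and Spearman rho = 0.866.

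The interaction of genotype with anti-IgM was called for Il4i1, an enzyme that oxidizes phenylalanine, and for the small RNA genes Snora31 and Mir18. Il4i1 (chromosome 7, 44816387 to 44840809) went from 52.6 ± 0.683 to 157 ± 1.67 FPKM in wild-type and from 41.6 ± 1.08 to 76.3 ± 2.32 FPKM in Trpm5-/- cells (SD, n = 2), a difference of responses of -0.70 ± 0.08 (limma adjusted p = 0.014, range 0.00589 to 0.133). It lost the call without Trpm5-/- unstimulated replicate 1 (adjusted p = 0.087), wild-type anti-IgM replicate 1 (0.079) or 2 (0.077) and Trpm5-/- anti-IgM replicate 1 (0.067) or 2 (0.13). Of 10797 genes 3 were called and 857 had an unadjusted p under 0.05 (limma). Next in order of p, and not called, were the aspartic protease gene Napsa at -0.60 and the serine and glycine enzyme gene Shmt2 at -0.43 (limma adjusted p = 0.065 each). In the other direction Kctd13 stood at 0.57 and Wsb1 at 0.36. The count was 7 and 5 without wild-type unstimulated replicate 1 and 2, 2 and 6 without the Trpm5-/- ones, 4 and 2 without wild-type anti-IgM replicate 1 and 2, and 2 and 2 without the Trpm5-/- ones. It was 9 without the filter on low values and 5 in a fit of the compared libraries alone.

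Set directly against each other in wild-type cells, LPS gave higher levels of the inflammatory cytokine genes Il1b and Il6, and anti-IgM higher levels of the transcription factor genes Egr2 and Nr4a2. Il1b stood at 91.4 ± 4.63 FPKM with LPS and 0.965 ± 0.347 FPKM with anti-IgM, and Il6 at 54.2 ± 1.36 and 0.382 ± 0.0543 FPKM (SD, n = 2). Egr2 stood at 9.23 ± 1.55 and 163 ± 9.68 FPKM. Of 20 cytokines and chemokines 15 were higher with LPS and 1 lower, 15 and 2 adjusted over the list alone (camera adjusted p = 6.02e-06, and adjusted p = 0.0133 with an estimated correlation). NF-kB targets were higher in 23 and lower in 2 of 27 cases, the same adjusted over the list alone (camera adjusted p = 3.27e-11, and adjusted p = 0.0133 with an estimated correlation). Activation surface proteins were higher in 16 and lower in 2 of 21, the same adjusted over the list alone (camera adjusted p = 4.6e-06, and adjusted p = 0.0133 with an estimated correlation). In the calcineurin-NFAT list 4 were higher with LPS and 11 lower of 17, the same adjusted over the list alone (camera adjusted p = 0.0154, but adjusted p = 0.0808 with an estimated correlation). Egr2 stood at -4.01 ± 0.11 and the nuclear receptor gene Nr4a2 at -2.60 ± 0.15. Calcium channels and pumps were higher in 1 and lower in 15 of 24 cases, the same adjusted over the list alone (camera adjusted p = 0.000356, but adjusted p = 0.0552 with an estimated correlation). Macrophage markers were higher with LPS in 2 of 10 cases and lower in 0, the same adjusted over the list alone (camera adjusted p = 0.301; 3 and 0 with quantile normalization), and dendritic markers were higher in 2 and lower in 1 of 3, the same adjusted over the list alone. In the RNA quality list 2 of 3 genes, Malat1 and Neat1, were lower with LPS, over all genes and adjusted over the list alone. Il6 at 5.32, the interferon-induced Cxcl10 at 4.30, the cytokine subunit gene Ebi3 at 4.07 and Dennd3 at 4.57 led the genes higher with LPS, together with Hba-a2, an erythroid globin gene with a wide spread (5.31 ± 1.95). Rab30, a small GTPase of the Golgi, at -4.13 and Neat1 at -3.99 were lower. In all, 2994 genes were higher and 2701 lower with LPS than with anti-IgM (limma, 5695 of 10797, 6294 at an unadjusted p under 0.05), 393 and 838 at least 2-fold.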

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

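All tests of explanations in this part were chosen after the result was seen, except the LPS control for neighbouring genes, the B-1 markers and the splits of the libraries. The next 2 paragraphs give results that stand out because the response to a stimulus differed between genotypes by a test of the interaction, and the list results all lost that call with an estimated correlation. The patterns weighed after them come from the averaged genotype difference.

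For LPS the log2 interaction (limma) was 1.653 for Lrmp, 0.8116 for Vps37b, 0.7422 for Pepd, -0.5783 for Gpr183, -0.4645 for Bid and -3.799 for Amd2. For Klk1b22 it was 2.481, for Snord33 10.82, for Mir324 8.777, for Snora31 5.482 and for Snord16a -10.27. For anti-IgM it was -0.6994 for Il4i1, -8.53 for Mir18 and 7.645 for Snora31. The values for Klk1b22 and the small RNA genes rest on groups listed at 0, depend on the pseudocount and bound nothing.

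Among gene lists the mean interaction with LPS was 0.096532 for NF-kB targets (camera adjusted p = 0.0125, but adjusted p = 0.197 with an estimated correlation). It was 0.27059 for interferon-stimulated genes (0.00079, and 0.343 with an estimated correlation) and -0.13678 for ribosome biogenesis (1.78e-05, and 0.105). Mitosis stood at -0.25977 (0.0167, and 0.197), glycolysis at -0.10177 (0.0488, and 0.197) and the unfolded protein response at -0.11156 (0.0372, and 0.197). Oxidative phosphorylation stood at -0.094217 and the ubiquitous reference list at -0.10748 (0.0191, and 0.343 for each), and macrophage markers at 0.39932 (0.0191, and 0.197). With anti-IgM the mean interaction was -0.12489 for B cell receptor signalling (camera adjusted p = 0.00369, but adjusted p = 0.201 with an estimated correlation) and -0.1286 for ribosome biogenesis (0.000241, and 0.178). Cell cycle entry stood at -0.1545 (0.0345, and 0.208) and macrophage markers at 0.40157 (0.00515, and 0.201). Over all genes no member of these lists was called for interaction with anti-IgM, and adjusted over the list alone 1 gene of B cell receptor signalling and 1 of ribosome biogenesis had a lower response and 1 macrophage marker a higher one. For LPS no member was called over all genes. Adjusted over the list alone, 3 NF-kB targets and 2 macrophage markers had higher responses and 2 mitosis genes and 2 genes of the unfolded protein response lower ones, and no members of the other lists did.

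Genes with large differences between genotypes lay near one another, as with Crebl2, Plbd1 and Mgst1 on chromosome 6 and Spib and Sult2b1 on chromosome 7. Of 42 called genes of at least 2-fold, 20 had another at 1 to 5 Mb, against a mean of 6.34 (SD 3.21) in 10000 random draws, a permutation p of 2e-04, with the 2-fold limit and the distances set after an exploratory look. This measures the pattern itself, so segments of another mouse strain left in the knockout genome stay open. Genes closer than 1 Mb did not count as neighbours of each other. Both still counted where a further gene lay at 1 to 5 Mb, as Gm8801 and A930015D03Rik did through Crisp3. The 20 also held the near-identical copies Amd1 and Amd2. Without Amd1 and Amd2 18 of 40 remained (mean of random draws 5.81, permutation p = 0.001), so reads shared between these copies are not the whole cause. Reads shared within other close pairs stay open. Only 8 of 42 genes with the largest LPS responses had another at 1 to 5 Mb, which argues against a general tendency of neighbours to change together. Strain segments could carry differences at genes like Spib that do not come from the loss of TRPM5, but no genotypes of the mice were used here, and 0 of the 42 lay within 10 Mb of Trpm5, where 13 of 82 tested genes were called (15.9 % against 16.1 % elsewhere, Fisher exact 2-sided p = 1). Some genes called for interaction lay on the same stretches. Lrmp (145115653 to 145174934) lay beside Stk38l (146724995) on chromosome 6, and Il4i1 (44816387 to 44840809) beside Spib (44525993) on chromosome 7. Bid and Pepd also lay on chromosomes 6 and 7, but Vps37b and Gpr183 on chromosomes 5 and 14. Itpr1 and Itpr2 lay near Il5ra and Stk38l on chromosome 6. Strain segments stay open for such genes too. Tspan32 and Cd81, which lie beside Trpm5 on chromosome 7, were lower in Trpm5-/- cells by less than 2-fold, so they are not among the 42. Whether the targeted allele itself lowers its neighbours was not tested. An effect of the channel on any of these genes was not tested and stays open.

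The marginal zone list, with Cd9 and Plxnd1, was higher and the follicular list, with Fcer2a, lower in Trpm5-/- cells. Cr2 and Cd1d1, both higher in marginal zone than in follicular cells, had a mean averaged difference of -0.129 ± 0.0615 (SE) against a pan-B median of -0.228, so fewer follicular B cells in the knockout sorts stay open, since a small share of such cells would barely move genes this high in marginal zone cells. Of 10 tested B-1 markers other than Il5ra 5 were higher and 5 lower in value, none called by limma, with a median of 0.0241 (SD 0.171). By the rule set beforehand, which used the median and the number called higher, these values go against more B-1 cells. That rule took no account of the spread between markers, which is too wide to exclude a small share of such cells. A change of marginal zone identity with the loss of TRPM5 was not tested and stays open, as do differences carried by linked segments.

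The mitosis list, with Top2a, and the ribosome biogenesis list, with Odc1, were higher in Trpm5-/- cells. The erythroid list had a median of -0.381, which argues against cycling erythroid precursors in the knockout sorts. The lists exceeded the ubiquitous reference list by 0.416 ± 0.0294 (mitosis) and 0.0737 ± 0.0216 (ribosome biogenesis; SE), which argues against scaling between libraries as the whole cause. More antibody-secreting cells could bring such RNAs and stay open, since 4 of 15 tested plasma cell genes other than Jchain were called higher, with a median of 0.101. An effect of the channel on growth and division was not tested and also stays open.

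The averaged genotype difference gave 1732 genes. Among 100 splits drawn from the 108 splits of the libraries within conditions, the real one included, only 1 gave as many, the real split, and the highest other split gave 169. Chance can be excluded for the count as a whole only if the libraries are independent, which the labels do not say, and otherwise only technical chance; it cannot be excluded for single genes such as Neat1, whose call ended without single libraries. Of the 100, 29 splits had 1 library of each genotype on each side in every condition, and the highest count among these was 5.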

How the results depend on the processing

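The fit without small RNA genes was added after the data were seen; all other alternatives were planned. Among the named genes that were called, directions held in every setting, except that with quantile normalization Eif2s3y had an LPS response of -0.2288 in wild-type cells and Hsp90ab1 a difference of -0.07024 between LPS and anti-IgM; the cause was not tested. The medians of 5 called lists turned with it: glycolysis and the ubiquitous reference list (genotype, anti-IgM) and oxidative phosphorylation (LPS in each genotype, and LPS against anti-IgM); the cause was not tested. Response counts stayed within 1.5 times. Fits of the compared libraries alone gave 21 genes for genotype under LPS, 116 under anti-IgM, 51 without stimulus and 5 for each interaction, with fewer libraries to estimate the spread. The interaction with anti-IgM gave 9 genes without the filter on low values and 5 with the robust spread model; the cause was not tested. Leaving out a library reduced the data: genotype under LPS fell to 158 to 206 genes, under anti-IgM to 119 to 156 and without stimulus to 159 to 274, and the interactions ranged from 3 to 23 (LPS; 23 without Trpm5-/- LPS replicate 1) and 2 to 7 (anti-IgM). Of 264 pairs of a list and a comparison camera called 128, and 43 stayed called with an estimated correlation. With replicate number as a block the interaction with LPS gave 6 genes and no other count moved by over 1.5 times. The differences between replicates 1 and 2 of a group correlated with those of other groups at -0.172 to 0.199, across genes. Without small RNA genes the genotype counts were 471 (LPS), 552 (anti-IgM) and 756 (no stimulus). Scaling by median ratios moved almost nothing, since the values were already scaled. Low-level genes such as Trpm5, at 40 fragments in 6 wild-type libraries, were left out by the filter on low values.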

Other observations

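No tests were run in this part beyond those of the report, and the genes here were chosen after their values were seen. In the averaged fit Camk4, a kinase activated by calcium and calmodulin, fell in Trpm5-/- cells by 1.01 (limma adjusted p = 7.6e-05), and Mcoln3, a calcium channel of endosomes, also fell (limma adjusted p = 0.0018). Ahr, which senses dietary and microbial ligands, rose by 1.02.

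The snoRNA host gene Snhg9 varied between libraries, with 9.35 and 0 FPKM in wild-type and 28.2 and 48.5 FPKM in Trpm5-/- cells without stimulus. With LPS it read 6.91 and 6.98 against 78.8 and 36.2 FPKM, and with anti-IgM 21.1 and 17.3 against 82.0 and 59.5 FPKM. Mir1898 was above 0 in 3 libraries, at 2318 and 827 FPKM in wild-type cells without stimulus and 2329 FPKM in 1 wild-type library with anti-IgM. Mir3061 read 343 and 270 FPKM in Trpm5-/- cells with anti-IgM and 273 FPKM in 1 wild-type library without stimulus, and was listed at 0 in the others. Mir19b-1 read 558 and 1755 FPKM in Trpm5-/- cells with anti-IgM and 1171 FPKM in 1 Trpm5-/- library without stimulus. The globin gene Hba-a2 lay between 0.853 and 299 FPKM across the 12 libraries.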
